A study of Danio rerio with 16 samples.

How the data were processed

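The series used several assays to look for long intergenic noncoding RNA genes of the zebrafish, Danio rerio. Of its 16 samples, 3 were analysed here, all made with 3P-Seq, a method that sequences the ends of polyadenylated RNA and so marks where poly(A) tails begin. They were wild-type whole embryos at 24 hours post fertilization (hpf), whole embryos at 72 hpf and whole adults of mixed gender, with 1 library per stage. The other 13 samples, which are chromatin immunoprecipitation, input and RNA-Seq libraries, were not analysed here.

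Each deposited file lists intervals of the genome with a strand and a whole number, taken here as the tag count, which the authors did not normalise as far as the values show. Tags were aligned with Bowtie to the Zv9 (danRer7) genome, per the submitters' processing notes, and the build is also named in the file headers. The Bowtie version, the trimming and any filter on the number of genomic matches are not given in the sources used here. The whole number stands in the name field of each deposited line. No label or header says what it is, and every count here rests on reading it as tags per interval. Also, the file headers give a display offset of 1, which was added to the positions. All positions below are 1-based danRer7 coordinates.

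The 3′ end of an interval was taken as its end on the plus strand and its start on the minus strand. This was checked on the files: on the plus strand of the 24 hpf library the intervals had 55967 distinct ends and 97066 distinct starts, and on the minus strand 54167 distinct starts and 94432 distinct ends, so the side taken as the 3′ end was the more shared in each case. Positions of the 3 libraries were pooled and clustered per strand. From the position with the most tags down, each position absorbed all unused positions within 10 nt, and clusters with at least 4 tags over the 3 libraries were kept. A cluster is named by its position with the most tags. It counted as detected in a library with at least 4 tags there.

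For each of the 3 pairs of libraries, tag counts were scaled to 1000000 tags per library (CPM), and their ratio was computed per cluster with at least 20 tags over the pair, with an exact conditional Clopper-Pearson 95% interval. A cluster was called higher or lower when the ratio was at least 4-fold and the interval excluded 2-fold. A library without tags was set to a floor of 3 tags and the fold given as a lower bound, so that in a ranking by fold a site without tags can stand below a site with 1 or 2 tags. Neighbouring clusters of the same strand 50 to 5000 nt apart made a tandem pair, measured by the share of its tags at the downstream site where both libraries had at least 20 tags. A shift was a change of at least 20 percentage points. Clusters within 100 nt of a cluster on the other strand were counted, with the minus strand moved by 20000 nt as a control. At this distance 3′ ends of opposite strands always belong to transcripts running toward each other, so no divergent class exists. For regions, bins of 500 kb with at least 20 tested clusters were listed when at least 70% of them were called in the same direction, a step chosen after the data were seen. Clusters with at least 1000 tags in a library were called near-equal to another cluster when their totals differed by at most 1.1 times and the chi-square per degree of freedom over their intervals was under 1.6, also a step chosen after the data were seen.

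With 1 library per stage there is no replicate check, no p-value is given, and every call compares these libraries and not the stages. Intervals and floors cover counting error only, and tags of the same molecule copied by PCR are not independent. To size this, intervals with no other interval within 10 nt of their 3′ end were taken as a rough stand-in for molecules. They held a mean of 3.74 tags at 24 hpf, 3.52 at 72 hpf and 1.23 in the adult, which makes intervals too narrow, most of all for the embryo libraries. Libraries with no difference but this duplication were simulated 10 times per pair, with tags per molecule drawn from such intervals up to their 99th percentile, and those counts stand beside the observed ones.

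The steps were tested on simulated data. All 5000 simulated sites were recovered as clusters. This does not show how a site is clustered when its ends spread past the clustering window. In the libraries, close clusters such as minus-strand 25203632 and 25203644 on chromosome 22 were kept apart, and whether they are separate sites was not tested. Among 27819 simulated clusters for 72 hpf against 24 hpf, drawn without duplication, 100 of 100 changed by 8-fold were called, 0 of 100 changed by 2-fold were called, and 1 unchanged cluster was called. For adult against 72 hpf (30075 clusters) and adult against 24 hpf (26068 clusters), 100 of 100 changed by 8-fold and 0 of 100 changed by 2-fold were called, with 2 unchanged clusters called in each. A change of 40 points was recovered in 200 of 200 tandem pairs in every comparison. Changes were placed only in clusters with at least 100 tags over the pair. For tandem pairs they were placed where each library had at least 100 tags, around an even split. Recovery at the 20 tags from which the rules act was thus not tested, and changes of 2-fold lie below the 4-fold rule.

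The stage comparisons, the size rule, the tandem rule and the rule for named sites were set before the data were examined. That rule names the 2 clusters with the largest fold in each direction among those with at least 100 tags over a pair, the 5 clusters with the most tags per library, and the 5 tandem pairs with the largest shift in each direction with at least 100 tags in each library. Of these tandem pairs, the text describes some and gives the range of shifts for each comparison and direction. Alternatives covered the clustering, the tag minimums, thinning, the set of chromosomes, the scaling, the size rule and the distances. No genome or annotation of the danRer7 build was used here, so clusters carry no gene names, and gene assignment, genomic place, sequence at clusters and gene lists were not analysed. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.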

Results

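Poly(A) sites were profiled by 3P-Seq in whole zebrafish at 3 stages, 24 hpf embryos, 72 hpf embryos and adults, with 1 library each. The 24 hpf library held 7423152 tags in 235580 intervals, the 72 hpf library 9813481 tags in 319885 intervals and the adult library 7470435 tags in 517701 intervals. Intervals with 1 tag made up 15.1%, 14.6% and 53.0% of the intervals, in that order. The 3′ ends fell at 370449 positions, which formed 90940 clusters, 45986 on the plus strand and 44954 on the minus strand. Clusters detected numbered 43472 at 24 hpf, 55814 at 72 hpf and 44480 in the adult. No stage has a replicate, and a count of 0 tags allows up to 0.404 CPM at 24 hpf, 0.306 at 72 hpf and 0.402 in the adult.

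The site with the most tags differed between the stages, though 2 sites stood among the leading 5 of more than 1 library. At 24 hpf, 3 minus-strand clusters on chromosome 12, at 17701282, 17962598 and 17784892, held 17919, 17882 and 17842 CPM (tag counts scaled to 1000000 tags per library), with 942, 935 and 944 at 72 hpf and 0.535, 0.402 and 0.268 in the adult. They were followed by minus-strand clusters on chromosome 19 at 5980626 (13495 CPM) and on chromosome 1 at 34340610 (11280.1). At 72 hpf the leading cluster lay on the minus strand of chromosome 17 at 758922 and took 5.03% of all tags (95% interval 5.01% to 5.04%), 5.82-fold its level at 24 hpf (interval 5.78 to 5.87). Next came chromosome 7 plus strand at 31296974 (24926 CPM), chromosome 3 minus strand at 61802779 (23584), chromosome 15 minus strand at 22997268 (13289) and the chromosome 19 site at 5980626 (12268). In the adult, plus-strand clusters on chromosome 20 at 54384260 and 54381041 held 17045 and 16987 CPM, against 6 tags each at 24 hpf and 0 at 72 hpf. The minus-strand cluster on chromosome 4 at 7210122 held 96283 adult tags and none in either embryo library, so it was at least 31891-fold higher than at 24 hpf and at least 42160.5-fold higher than at 72 hpf. The adult list closed with minus-strand clusters on chromosome 6 at 33608800 (12255 CPM) and on chromosome 17 at 758922 (12219). Tag counts were near-equal among the chromosome 12 sites at 24 hpf (133019, 132740 and 132444) and between the chromosome 20 plus-strand sites in the adult (127331 and 126903).

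The comparison of detected sites asks how far the stages share their poly(A) sites. All 3 libraries detected 20994 clusters, 23.1% of the total, and these held 87.4% of the tags at 24 hpf, 92.6% at 72 hpf and 66.6% in the adult. Clusters detected in 1 library alone numbered 13005 for 24 hpf, 22409 for 72 hpf and 15494 for the adult, with a median of 7 tags over the libraries in each set. The adult-only clusters held 16.4% of the adult tags, whereas the 24 hpf-only clusters held 1.44% and the 72 hpf-only clusters 2.12% of the tags of their own library. A further 6946 clusters were detected in both embryo libraries and not in the adult. Another 2527 were detected at 24 hpf and in the adult but not at 72 hpf. They held 11.1% of the adult tags and 0.41% of the 24 hpf tags. Among them were the chromosome 20 plus-strand sites at 54384260 and 54381041, detected at 24 hpf by only 6 tags each. When detection asked for at least 10 tags, the sets of 1 library fell to 4676, 9348 and 7453 clusters, so most clusters of these sets rest on few tags. The order of the sets depended on how detection was defined: with at least 2 distinct intervals in a library, a setting chosen after the data were seen, the adult-only set was the largest, at 19987 clusters against 3644 for 24 hpf and 8028 for 72 hpf. With each library thinned to the depth of the 24 hpf library, 43469 clusters were detected at 24 hpf, 48509 at 72 hpf and 44318 in the adult. Of these, 20482 were shared by all libraries, and 13700, 16967 and 16065 were detected in 1 library alone, in the same order.

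**Figure D1:**
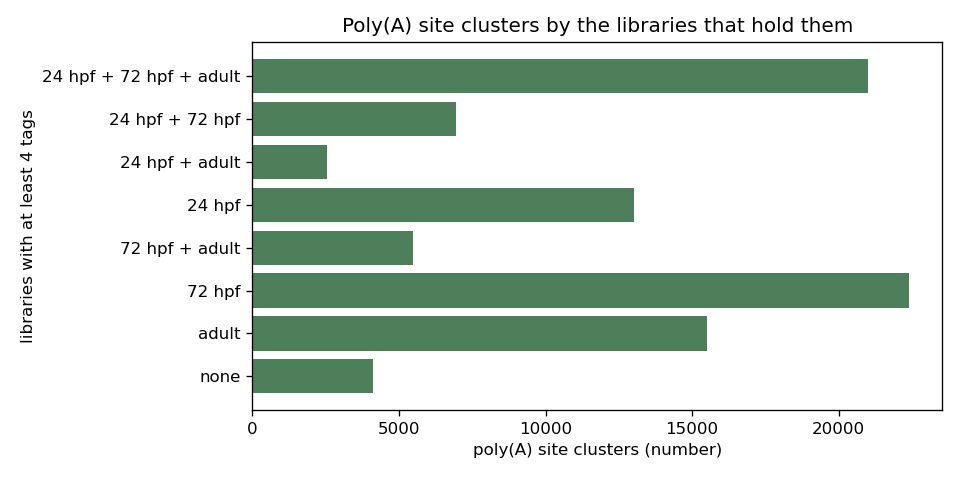
Number of poly(A) site clusters (horizontal axis) for each combination of libraries that held at least 4 tags (vertical axis). The longest bars are the 22409 clusters of 72 hpf alone and the 20994 clusters of all libraries.

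Between 24 hpf and 72 hpf, 2 regions passed the rule for regions. On chromosome 9 between 23.0 and 23.5 Mb, 38 of 47 tested clusters were higher at 72 hpf and 0 lower, and the region went from 189 to 4805 CPM, a 25.4-fold ratio (95% interval 24.1 to 26.8). On chromosome 12 between 17.5 and 18 Mb, 30 of 34 tested clusters were lower at 72 hpf and 1 was higher, and the region fell from 7.99% of all tags to 0.347%. In it, 8 minus-strand clusters, each near-equal to another cluster though not all to each other, held 72222 of its 79930 CPM at 24 hpf. They ranged from 916 to 17919.5 CPM, and the partner of the cluster at 17825928, at 18005763, lay outside the region. The rest of the region fell from 7708 to 251 CPM. Of the 7708 CPM, 7205 lay in 3 clusters, at 17586055, 17684092 and 17659527, and the other clusters fell from 503 to 59.9 CPM. Near-equal clusters were looked for only from 1000 tags, and smaller ones such as 17809701 and 17986301 (54.4 and 54.3 CPM) lay beside them, so the 30 calls need not be separate sites. Among clusters with at least 100 tags, the folds ranked highest were 797 (interval 220 to 6585) for the chromosome 9 minus-strand site at 23350948 and 507 (interval 90.7 to 20047) for the chromosome 23 plus-strand site at 17947897. The folds lower were led by 533 (interval 95.1 to 21095) for the chromosome 12 minus-strand site at 17986301 and 286 (interval 78.6 to 2365) for the chromosome 22 minus-strand site at 10223024. These 4 ratios rest on 1 or 2 tags in the lower library, whereas a library without tags was set to 3. With every count under 3 set to 3, an order chosen after the data were seen, the chromosome 9 site and the chromosome 12 plus-strand site at 14367790 led the higher folds. The lower folds were then led by plus-strand sites without tags at 72 hpf, on chromosome 25 at 23058621 (at least 273-fold) and chromosome 12 at 18018783 (at least 215-fold).

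Over all 27819 tested clusters, 5601 were higher and 2223 lower at 72 hpf. Simulated libraries without a difference but with the measured duplication gave a mean of 898 higher and 758.7 lower calls, and intervals built from estimated molecules left 2567 higher and 1107 lower. The regions were chosen after the data were seen, as the only ones of 307 bins that passed the rule for this pair.

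Between 72 hpf and the adult the same chromosome 9 region went the other way, with 39 of 54 tested clusters lower, 9 higher and 278 CPM in the adult. On chromosome 22 between 25 and 26.5 Mb, 83 of 97 tested clusters were higher in the adult and 5 lower, and the region rose from 172 to 53801 CPM, 314-fold (95% interval 299 to 329) and 204-fold without its 2 leading clusters. Close clusters were counted separately, such as minus-strand 25203632 and 25203644 (5507 and 28.0 adult CPM), so these calls need not be separate sites. With a 24 nt window the chromosome 22 bins still passed the rule, with 20 of 24, 24 of 29 and 36 of 41 clusters higher. Close clusters also stood in the chromosome 9 region, such as 23124494 and 23124505, and in the chromosome 4 region below, such as 61138019 and 61138032. On chromosome 4 between 60.5 and 61.5 Mb, 31 of 53 tested clusters were higher and 5 lower, and the region rose 17.1-fold (interval 16.5 to 17.8); only its bin from 61 Mb passed the rule for this pair. Of its 4773 adult CPM, 3638 lay in 5 minus-strand clusters between 61123939 and 61142645, each near-equal to another of them (661 to 821 CPM). Without them the ratio was 4.07 (interval 3.90 to 4.25) and the bin no longer passed, with 16 of 25 clusters higher. Without the 3 leading clusters of the rest, among them 61147431 beside the near-equal ones (0 to 585 CPM), the ratio was 2.3 (interval 2.18 to 2.43). On chromosome 19 between 5.5 and 6 Mb, 21 of 29 tested clusters were lower, and the region fell from 21299 to 920 CPM. Most of this sum lay in 2 minus-strand clusters, at 5980626 (12268 to 1.74 CPM) and 5963568 (6635 to 73.1). Without them it went from 2396 to 845 CPM, 2.84-fold lower (interval 2.76 to 2.92). Without the next cluster as well, at 5986769 (958 to 0 CPM), it went from 1438 to 845 CPM, 1.70-fold lower (interval 1.65 to 1.75). This region did not pass the 70% rule with median-ratio scaling (17 of 29 lower), libraries thinned to the smallest (18 of 26), intervals from molecules (18 of 29) or the 8-fold rule (11 of 29). With the 8-fold rule the chromosome 9 region (36 of 54) and the chromosome 4 bin (20 of 30) did not pass it either, and with a 24 nt window, single linkage or intervals from molecules the chromosome 4 bin did not (17 of 27, 17 of 26 and 20 of 30). The largest folds higher were at least 55756 and at least 55568, for the chromosome 20 plus-strand sites at 54384260 and 54381041. The largest folds lower were 7050 (interval 4122 to 13240.0) for the chromosome 19 minus-strand site at 5980626, with 13 adult tags, and at least 7017 for the chromosome 3 plus-strand site at 55983728.

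Of 30075 tested clusters, 5734 were higher and 8386 lower in the adult. The simulation without a difference gave 138.1 higher and 222.6 lower calls. The excess of lower calls depended on the scaling: median-ratio scaling raised every log2 ratio of this pair by 0.39 and gave 6576 higher and 6566 lower. The 8-fold rule gave 4073 higher and 3735 lower. Regions were again chosen after the data were seen, from 374 bins.

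The adult set against 24 hpf showed the chromosome 22 region again, with 82 of 94 tested clusters higher and 2 lower, 245-fold over the region (95% interval 233 to 257) and 159-fold without its 2 leading clusters. With intervals from molecules, its bins had 16 of 24, 18 of 30 and 26 of 40 clusters higher, below the 70% rule. In the chromosome 12 region 30 of 32 tested clusters were lower and 0 higher, and its level fell from 79930 to 54.6 CPM, or from 7708 to 53.1 without the near-equal clusters. Without those 3 leading clusters as well, it went from 503 to 53.0 CPM, 9.48-fold lower (interval 8.55 to 10.5). In the chromosome 4 region, 37 of 63 tested clusters were higher and 12 lower, with an 11.1-fold ratio (interval 10.7 to 11.5). Without the near-equal clusters the ratio was 2.80 (interval 2.69 to 2.92). Only the bin from 60.5 to 61 Mb passed the rule for this pair (17 of 21 higher), though not with intervals from molecules (14) or the 8-fold rule (11), and from 61 Mb 20 of 42 were higher and 12 lower. By the ranking used, the folds higher were led by 54408 (interval 9765 to 2149060) for the chromosome 16 plus-strand site at 28254287 and 32339.5 (interval 8952 to 267043) for the chromosome 20 minus-strand site at 54368478, which rest on 1 and 2 tags at 24 hpf. With every count under 3 set to 3, they were led by sites without tags at 24 hpf, the chromosome 4 minus-strand site at 7210122 (at least 31891-fold) and the chromosome 22 plus-strand site at 26273793 (at least 26690.0-fold). The folds lower were led by 66644 (interval 18448 to 550305) and 44528 (interval 15236 to 215926), for the chromosome 12 sites at 17784892 and 17962598, with 2 and 3 adult tags. With the floor for every count under 3, the site at 17962598 led (44528) and that at 17784892 came next (44429).

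Of 26068 tested clusters, 6138 were higher and 5270 lower in the adult, against 214.5 and 314.7 in the simulation without a difference. Which direction held more clusters changed with the setting: with molecules in place of tags, 3915 were higher and 4573 lower, and with the 2-fold rule 8762 were higher and 8958 lower. Median-ratio scaling raised every log2 ratio of this pair by 0.30 and gave 6737 higher and 4390 lower, and for 72 hpf against 24 hpf it moved the ratios by -0.09.

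**Figure D2:**
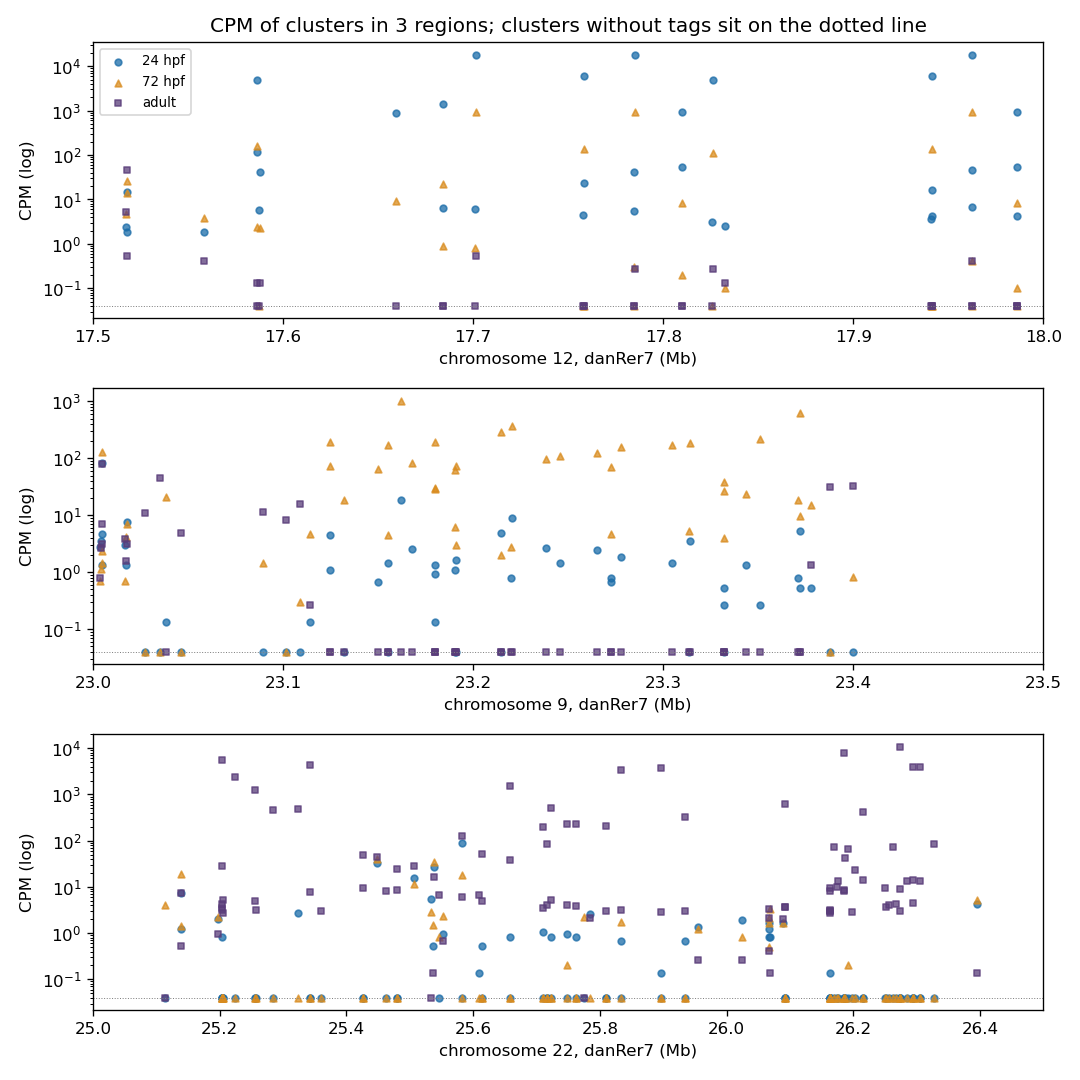
CPM on a log axis (vertical) of clusters with at least 20 tags in regions of chromosomes 12, 9 and 22 (horizontal, danRer7 positions in Mb), with circles for 24 hpf, triangles for 72 hpf and squares for the adult; clusters without tags in a library sit on the dotted line. The chromosome 12 region held 7.99% of the 24 hpf tags, the chromosome 9 region 4805 CPM at 72 hpf and the chromosome 22 region 53801 in the adult.

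Chromosome M took 3.00% of the tags at 24 hpf (95% interval 2.99% to 3.02%), 4.16% at 72 hpf (4.15% to 4.18%) and 2.57% in the adult (2.56% to 2.58%). Its sites did not move together. The plus-strand cluster at 10518 went from 5023 CPM at 24 hpf to 11429 at 72 hpf and 6436 in the adult, and the cluster at 10938 was 3.23-fold higher at 72 hpf than at 24 hpf (interval 3.17 to 3.29). The cluster at 950 went the opposite way, from 7918 at 24 hpf to 4029 at 72 hpf and 1910 in the adult. On the minus strand, the cluster at 4923 held 58 tags at 24 hpf, 164 at 72 hpf and 4009 in the adult, 68.7-fold higher in the adult than at 24 hpf (interval 53.0 to 90.6). These sites were chosen after their values were seen.

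**Figure D3:**
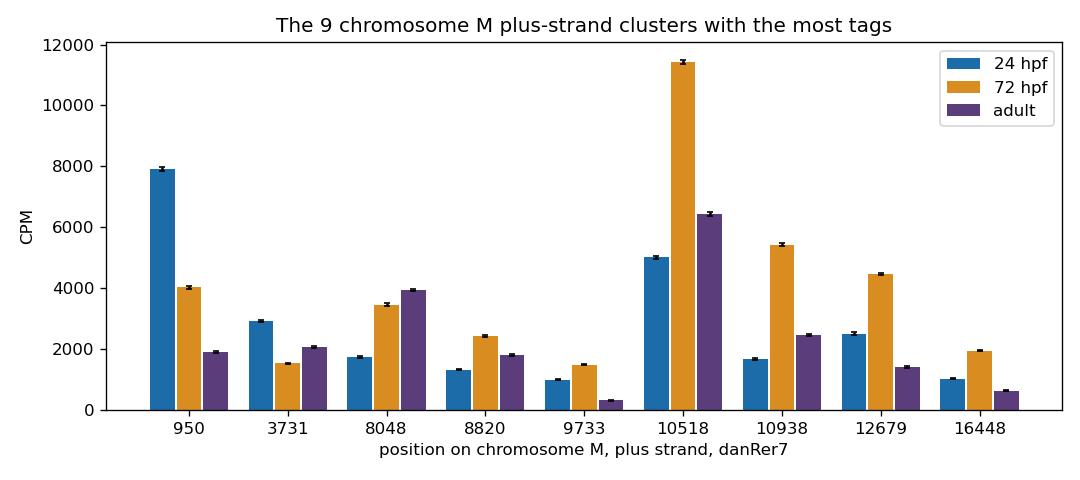
CPM (vertical axis) at the 9 plus-strand clusters of chromosome M with the most tags over the libraries (horizontal axis, danRer7 position), with exact binomial 95% intervals that cover counting error only. The cluster at 10518 was tallest at 72 hpf (11429) and the cluster at 950 at 24 hpf (7918).

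Tandem site use asks whether transcripts with neighbouring poly(A) sites shift between them. Without gene annotation, both sites of a pair may also belong to different genes, above all in pairs far apart, such as the first one named below (3314 nt). In the adult against 72 hpf, shifted pairs mostly moved to the upstream site: of 10949 measured pairs, 1281 moved upstream and 337 downstream, so 79.2% of the shifted pairs went upstream. On chromosome 7, plus strand, the pair at 51170870 and 51174184 had 98.3% of its tags at the downstream site at 72 hpf (95% interval 97.0% to 99.1%) and 5.34% in the adult (2.18% to 10.7%). The chromosome 21 plus-strand pair at 2719645 and 2720976 went from 97.3% (93.2% to 99.3%) to 6.90% (3.99% to 10.96%). In the other direction, the chromosome 5 plus-strand pair at 29078803 and 29078866 had 0 of 129 tags downstream at 72 hpf (interval up to 2.82%) and 95.2% in the adult (92.4% to 97.2%). The chromosome 13 plus-strand pair at 32677533 and 32679885 went from 1.67% (0.202% to 5.89%) to 83.0% (76.6% to 88.2%).

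Against 24 hpf, 1000 of 9868 pairs moved upstream in the adult and 404 downstream. The largest upstream shift was again that of the chromosome 7 pair at 51170870, from 99.5% downstream (95% interval 99.1% to 99.7%) to 5.34%. The chromosome 21 plus-strand pair at 20706727 and 20707318 went from 81.4% (75.8% to 86.2%) to 0 of 549 tags (up to 0.670%). The chromosome 11 minus-strand pair at 37098891 and 37095074 moved downstream, from 13.1% (10.6% to 15.99%) at 24 hpf to 85.5% (83.9% to 87.0%) at 72 hpf and 94.9% (92.1% to 97.0%) in the adult. Among pairs with at least 100 tags in each library, the 5 largest upstream shifts spanned 78.5 to 93.0 points for the adult against 72 hpf and 74.2 to 94.1 for the adult against 24 hpf, and the 5 largest downstream shifts 75.5 to 95.2 and 45.7 to 81.8. Between the embryo libraries they spanned 44.6 to 92.3 points upstream and 47.2 to 72.3 downstream. Between the embryo libraries 637 of 12666 pairs moved upstream and 906 downstream. There the largest upstream shift, the chromosome 5 minus-strand pair at 32174909 and 32173715, went from 95.2% (93.2% to 96.8%) to 2.88% (1.07% to 6.17%) and stood at 83.1% in the adult (78.6% to 87.1%).

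In simulated pairs with no change of site use but the measured duplication, a mean of 238 pairs moved upstream and 238.7 downstream for the adult against 72 hpf, 233.1 and 259.3 for the adult against 24 hpf, and 516.3 and 521.3 for 72 hpf against 24 hpf. For 72 hpf against 24 hpf, a large part of the observed 637 and 906 shifts was thus matched by duplication alone. Pairs with at least 200 tags in each library gave 90 upstream and 7 downstream shifts for the adult against 72 hpf, and 12 and 20 for 72 hpf against 24 hpf.

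**Figure D4:**
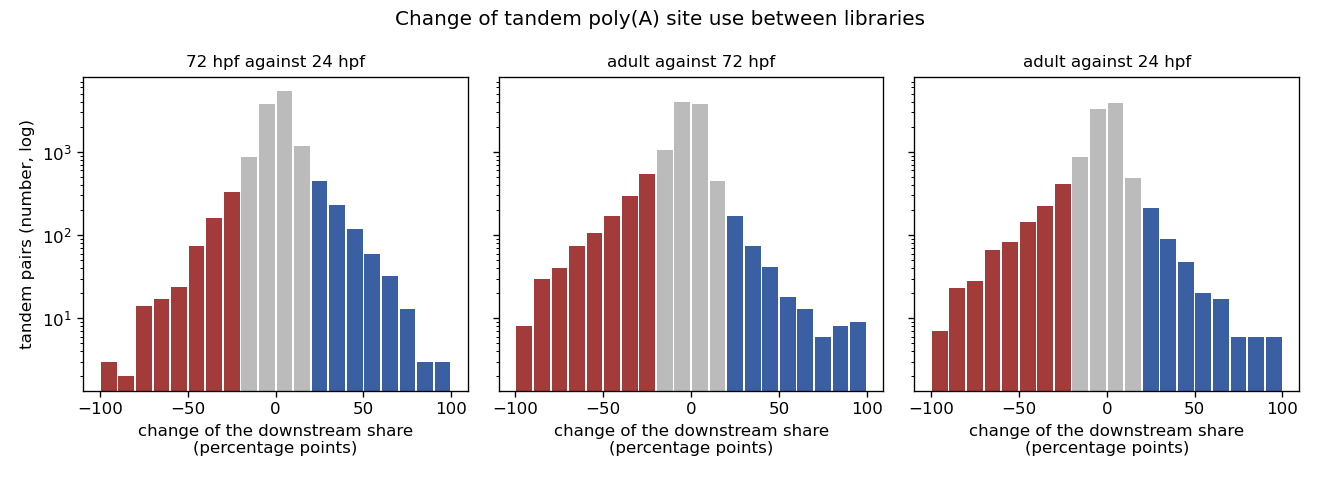
Number of tandem pairs on a log axis (vertical) by the change of the downstream share in percentage points (horizontal) for each pair of libraries, with upstream shifts of at least 20 points in red and downstream ones in blue. For the adult against 72 hpf the red side holds 1281 pairs and the blue side 337.

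Transcript ends that face each other on opposite strands were more frequent than with shifted strands. Leaving out chromosome M, 3252 of 89825 clusters (3.62%) lay within 100 nt of a cluster on the other strand, against 579 (0.645%) with the minus strand moved by 20000 nt. Their pairs comprised 1418 whose ends lay apart and 900 whose transcripts overlapped. By library, 2.81% of the detected clusters at 24 hpf, 3.26% at 72 hpf and 3.01% in the adult had such a neighbour. On chromosome M, where clusters are dense on both strands, 1070 of 1115 clusters had one, and the shifted control matched 0 there and is no measure of chance. With chromosome M, as first planned, 4322 clusters (4.75%) had a neighbour, in 2930 pairs apart and 2382 overlapping. Leaving it out was chosen after the data were seen.

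Within clusters, the leading position was mostly the same in the libraries. Clusters were built within 10 nt of the leading position of the pooled libraries, so larger moves fall into other clusters. The agreement is thus partly set by the clustering, and no value without a change was computed. In the 3693 clusters with at least 100 tags in every library, the position with the most tags held a median of 81.2% of the cluster at 24 hpf, 81.2% at 72 hpf and 80.3% in the adult. That position was identical in 3446 clusters (93.3%) for 72 hpf against 24 hpf, in 3424 (92.7%) for adult against 72 hpf and in 3372 (91.3%) for adult against 24 hpf.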

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

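Alternatives with at least 200 tags per tandem pair, 2 distinct intervals, estimated molecules, no copies, no short intervals and no chromosome M were chosen after the data were seen. Of 217 recomputed counts, 163 stayed within 1.5 times the reported value and 54 did not. Of 420 ratios and shifts of named sites and pairs sought under the alternatives, 64 could not be had, 60 of them for tandem pairs. In those cases the setting left out the site or broke up the pair. Of the remaining 356, 0 changed direction. Many settings, such as other tag minimums, other pair distances or leaving out copies, can drop a named site or pair but cannot change its value. The named sites were also picked for extreme values, so the absence of reversals says little. For the counts that moved the cause was not tested beyond what each setting removes. Clusters of at least 10 tags left 50869 clusters, with 3480, 6401 and 5588 in 1 library alone (24 hpf, 72 hpf, adult). Detection at 1 tag gave 8637 and 14401 for 24 hpf and 72 hpf alone, detection at 10 tags 4676, 9348 and 7453 for the libraries in order, and detection by 2 distinct intervals 3644 and 8028 for 24 hpf and 72 hpf but 19987 for the adult, which then had the most.

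With the 2-fold rule, 72 hpf against 24 hpf gave 9766 higher and 5227 lower, adult against 72 hpf 13147 lower and adult against 24 hpf 8762 higher and 8958 lower, against the reported order. With the 8-fold rule these were 2477 higher and 1026 lower, 3735 lower, and 3848 higher and 2513 lower. Intervals from molecules gave 2567 higher and 1107 lower for 72 hpf against 24 hpf and 3915 higher for adult against 24 hpf. Under the 8-fold rule adult against 72 hpf had 4073 higher, more than lower, unlike the reported rule.

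Tandem shifts are given as upstream and downstream. With clusters of at least 2 tags, 839 and 665 moved upstream for the adult against 72 hpf and against 24 hpf. Pairs from 200 nt apart gave 398 upstream for 72 hpf against 24 hpf, 191 downstream for adult against 72 hpf, and 664 and 246 for adult against 24 hpf. A shift of 10 points gave 1501 and 2072, 2356 and 789, and 1871 and 886 for 72 hpf against 24 hpf, adult against 72 hpf and adult against 24 hpf. A shift of 30 points gave 299 and 457, 738 and 168, and 585 and 193, and pairs of at least 200 tags 12 and 20, 90 and 7, and 71 and 13. Adult shifts ran mainly upstream under every setting tried, and those between the embryo libraries mainly downstream. A 24 nt window or single linkage reduced the shift of the chromosome 10 minus-strand pair at 14571345 from -55.5 to -8.25 points and that of the chromosome 12 minus-strand pair at 28778149 from -74.2 to -23.3.

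Opposite-strand neighbours within 50 nt made 1557 pairs apart and 1274 overlapping, within 500 nt 8300 clusters with 11684 apart and 10008 overlapping, and without chromosome M 1418 and 900. Other gene assignment windows, genomic place, sequence at clusters and gene lists were not run, as no danRer7 genome or annotation was used here. Depth limits what can be said of clusters with few tags, and clusters under 20 tags over a pair of libraries were not compared. With 1 library per stage no library could be left out.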

Other observations

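The control with partners drawn at random and the second thinning of the adult library were chosen after a result was seen; the other tests below were set before their results were seen, though the patterns were found in the same libraries. No biological explanation was tested, since with 1 library per stage the stage itself cannot be.

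The first pattern is the move to upstream sites in the adult against 72 hpf, 79.2% of shifted pairs. Simulated libraries with the measured depth and duplication gave 49.9% upstream. Both were drawn from the same pooled site shares, so a near-even split was built in and says nothing on direction. Their mean of 238 upstream shifts, against 1281 observed, does argue against noise as the main source. Pairs up to 500 nt apart, which are less likely to join different genes, gave 77.1% (95% interval 74.2% to 79.8%). Pairs with at least 10% of tags at each site in both libraries gave 79.5% (76.0% to 82.8%). These shares argue against mixed genes and against background upstream sites found only in the adult. Background present in both libraries passes that filter and was not tested. Intervals in this paragraph treat pairs as separate trials, though neighbouring pairs can share a cluster, and do not measure spread between libraries. A planned control with same-strand clusters 20000 to 100000 nt apart gave 38.0%, outside both of its predicted ranges; why was not tested, and it decided nothing. With partners drawn at random the share was 46.4% (44.9% to 47.8%), so unrelated distant pairs showed no upstream skew. Exchanging upstream and downstream would hardly change the share of unrelated pairs, so this control cannot decide on strand handling. Also open is a difference between stages or between the ways the embryo and adult material was prepared, which 1 library per stage cannot separate. So is priming inside transcripts, which needs the genome sequence.

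A further pattern is the number of sites with few tags in the adult, whose own clusters with any tag (positions up to 10 nt apart joined) numbered 144200 against 63102 at 24 hpf, 2.29 times as many. Fewer distinct molecules in the embryo libraries may account for much of this. Thinned to 1982509 tags, the estimated molecule number at 24 hpf, the adult library had 1.18 times as many clusters as the 24 hpf library. Thinned to 2232034 tags, which hold about as many estimated molecules, it had 1.25 times as many, past the bound of 1.2 set in advance. The readings of the same test fall on either side of that bound, so whether molecule number is the whole cause was left undecided.

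The last pattern is the set of distant clusters with near-equal counts, such as the chromosome 12 sites at 17701282, 17784892 and 17962598 with 133019, 132444 and 132740 tags at 24 hpf. Of clusters with at least 1000 tags, 30 of 959 at 24 hpf, 37 of 1304 at 72 hpf and 41 of 870 in the adult had such a partner in any library. In all, 64 clusters had a partner in any library, and they held 8.47%, 1.03% and 5.64% of the tags in that order. A candidate explanation is that reads matching several copies were placed at random. Pairs picked in an embryo library were compared interval by interval in the other embryo library, where separately made molecules with the measured duplication would differ more than random placement allows. The median chi-square per degree of freedom over 33 such tests was 0.931 (quartiles 0.718 and 1.11), and 0 exceeded 2, as random placement would give. The tests are not separate: pairs picked in both embryo libraries entered once for each, and the chromosome 12 sites named above formed linked pairs. Levels of the sites tested in this way, those of chromosome 12 among them, may then be sums over copies divided among them. The pairs of chromosomes 4 and 20 were picked in the adult alone and have no such test, so for them this stays open. Without the 64 clusters, 5598 were higher and 2207 lower for 72 hpf against 24 hpf. Leaving them out could move the calls by 64 at most. Copies were looked for only from 1000 tags, so this does not show how far copies affect the calls.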
